A study of Caenorhabditis elegans with 2 samples.

How the data were processed

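Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole young adult hermaphrodites of the Caenorhabditis elegans strain OP543, collected 64 hours after synchronization by L1 starvation. The animals carried a transgene that encodes SDZ-38 with a C-terminal GFP-FLAG tag, and the description names an anti-GFP antibody used on sonicated chromatin. The antibody field of the labels reads sdz-38 instead, and the description is followed here. The labels give 2 biological replicates of this 1 group. No second group was analysed here, so the peak lists are described and set against shifted positions in the genome, and no condition was compared with another.

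The deposited files are lists of genomic regions in narrowPeak layout, given for genome builds ce10 and ce11. Per the file notes deposited with them, each replicate has a lenient list of peaks and background made from its alignment and one control alignment, a pooled list was made from both replicates together, and an optimal list was made from these by the irreproducible discovery rate (IDR) procedure. IDR weighs how well the ranks of regions repeat between replicates, and single optimal peaks can still rank far apart in them. The authors' signal value of each region is a score whose scale is not stated, and it was used to rank regions, to describe them and for the rank correlation. A two-sided permutation test compared the median signal values of nuclear peaks beside short RNA genes and elsewhere. The column that the narrowPeak layout assigns to −log10 q was used as deposited and applied as no filter. How the authors made these −log10 values before deposit is not stated. The aligner, the peak caller and their versions are not given in the sources used here. Signal tracks, alignments and the control library are not analysed here, so the sequencing depth behind each region is unknown. The precision of each share is set by the number of peaks, and exact Clopper-Pearson 95% intervals cover counting error only.

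The main coordinates are those of build ce11. Every region end of the ce11 lists lay within the chromosome lengths of the WBcel235 reference genome, whose RefSeq annotation gave the genes, their classes and their positions. Lists of build ce10 were used in their own coordinates for the number of peaks, the share on X and the overlap of the replicates, with the WBcel235 chromosome lengths for the shifts. No coordinate was converted between builds. All positions are 1-based. Nuclear peaks are those on chromosomes I, II, III, IV, V and X. The mitochondrial genome is a separate sequence in both the files and the reference.

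Summits were placed in promoters (1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene) and in 6 feature classes taken in the order promoter, coding exon, UTR, intron, non-coding RNA gene and intergenic. They were also counted within 250 bp of tRNA, snRNA, snoRNA, rRNA, miRNA and piRNA genes. Here the first 5 of those classes are called short RNA genes. Each count was compared with 10000 circular shifts of the summits within their chromosome, as a one-sided permutation test whose smallest p is 0.0001. The overlap of the replicates' strongest regions was tested by the same kind of shift of replicate 2. Shares on X and in the middle one of 3 equal parts of each chromosome were tested by two-sided exact binomial tests. A gene was counted as bound when a summit lay within 1000 bp of its 5′ end, and 24 gene lists were tested with two-sided Fisher's exact tests against 19971 nuclear protein-coding genes. Words of 6 bases within 50 bp of summits were compared with windows centred 300 bp to either side by Fisher's exact test. Families of tests were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The rank correlation of the replicates runs over peaks, which are not independent replicates, and its interval comes from 2000 bootstrap draws of peaks.

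The genes named were chosen by a rule fixed before the data were examined. It takes the 25 peaks with the highest signal value and a protein-coding 5′ end within 1000 bp of each, up to 4 bound members of each gene list past the threshold, up to 3 genes of each RNA class past the threshold, and always sdz-38 and unc-119, the usual rescue marker of such strains. The mitochondrial genome took 21 of those 25 places. The 25 strongest nuclear peaks and the other nuclear peaks named below were added after their values were seen. The alternatives fixed before the data were examined were the ce10 lists, the stronger 51 peaks, each replicate's own 102 strongest regions, other distances and windows, other references and another control sequence. Alternatives with nuclear peaks alone, with peaks away from short RNA genes and with the densest stretch of X counted once were added after seeing the data.

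The procedures were tested on simulated data before use. With 81 simulated summits, 5 of them placed at snoRNA genes, the snoRNA class was recovered in 100 of 100 sets, and 3 of 100 sets without placed summits gave any class past the threshold. A word placed in 15 of 81 windows was recovered in 20 of 20 sets. A list with 5 placed members among 40 bound genes was recovered in 100 of 100 sets, while 5 of 100 random sets gave any list. With 10 shared regions placed, 20 of 20 sets passed the overlap test, and 0 of 20 sets of independent regions did. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.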

Results

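Where the anti-GFP ChIP signal lay on the chromosomes of young adult worms with tagged SDZ-38 was read from the deposited peak lists of 2 biological replicates. Whether each peak marks SDZ-38 itself is not established, as no library without the tagged protein is analysed here. sdz-38 belongs to the genes named for SKN-1-dependent zygotic expression, and RefSeq describes its product as a C2H2-type domain-containing protein. The optimal list of build ce11 held 102 peaks, 81 of them nuclear and 21 mitochondrial. The optimal list of build ce10 held 94 peaks, 73 of them nuclear. The lenient lists of build ce11 held 17743 regions in replicate 1, 12648 regions in replicate 2 and 1242 regions in the pooled list. All 102 optimal peaks were regions of the pooled list. The median width of an optimal peak was 456 bp. Read as −log10 q, the column that the file layout assigns to q gave no region of any list a q of 0.05 or less. In the optimal list 68 of the 102 peaks tied at its smallest value, 0.126, and how the column was made is not stated.

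The 21 strongest peaks all lay on the mitochondrial genome. Their signal values ran from 199 to 4821, against 62.6 to 165 for the nuclear peaks. The strongest, at 4270 to 5217 of the mitochondrial genome, had its summit at 4714 in CYTB, which encodes cytochrome b, 210 bp from the gene's 5′ end and within 250 bp of the tRNA-Phe gene. The next lay in ND5 at 12142 to 12654 with a signal value of 4025, and in COX3 at 5837 to 6345 with 2740. A peak in ND4, at 7033 to 7488, reached 1540, and a peak in COX2, at 10026 to 10347 beside the tRNA-His gene, reached 1330. Peaks with signal values of 1058 and 936 lay in ND1 and ATP6, the latter beside the tRNA-Lys gene. Other mitochondrial peaks lay in COX1, ND2 and both rRNA genes. Together the 21 peaks covered 6839 of 13794 bp, or 49.6% of the mitochondrial genome. Regions of replicate 1 covered 39.3% of it and regions of replicate 2 covered 44.6%. The mitochondrial genome makes up 0.0138% of the reference length, and 20.6% of the optimal peaks lay on it (exact 95% interval 13.2% to 29.7%).

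Away from the mitochondria, the peaks gathered at genes for short non-coding RNAs. Of the 81 nuclear peaks, 44 (54.3%) had their summit within 250 bp of a tRNA, snRNA, snoRNA, rRNA or miRNA gene, against a mean of 0.721 peaks for shifted positions (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). The summit lay inside the gene in 17 of these 44 peaks, and the median distance to the gene was 13 bp. tRNA genes lay beside 20 nuclear peaks, snoRNA genes beside 16, snRNA genes beside 7 and miRNA genes beside 2. The shifted positions gave means of 0.374, 0.165, 0.0454 and 0.132. The adjusted p over 6 classes was 0.0002 for the tRNA, snoRNA and snRNA classes and 0.0105 for miRNA genes, by the one-sided permutation test. No nuclear peak lay beside an rRNA or piRNA gene. Shifted positions gave means of only 0.0116 and 1.27 for these classes, so this absence says little.

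**Figure D1:**
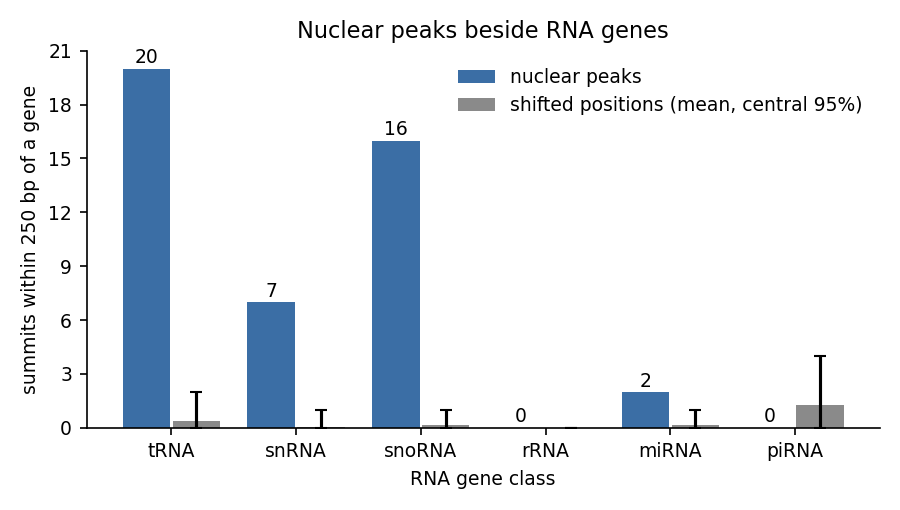
Number of the 81 nuclear peaks whose summit lies within 250 bp of a gene of each RNA class (blue bars), with the mean and central 95% range of 10000 circular shifts (grey bars with whiskers). The counts are 20 for tRNA, 7 for snRNA, 16 for snoRNA, 2 for miRNA and 0 for rRNA and piRNA genes.

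The strongest nuclear peak, on chromosome V at 8500322 to 8500777, had a signal value of 165 and lay in an intron of pxn-1, which encodes a peroxidasin, beside the snoRNA gene ZK994.7 (8500579 to 8500645). The second, on chromosome V at 12303399 to 12303854 with a signal value of 158, lay in an intron of frm-7 and had its summit within the snoRNA gene C51F7.4 (12303599 to 12303693), with C51F7.3 next to it. The third, on chromosome I at 13463779 to 13464234 with a signal value of 117, had its summit within rpr-1 (13463955 to 13464207), the gene for the RNA of RNase P, in an intron of the Integrator subunit gene ints-8. The fourth, on X at 9743469 to 9743924 with a signal value of 117, lay in an intron of the hemicentin gene him-4 between 2 genes for tRNA-Ala, F15G9.t1 and F15G9.t2. None of these 4 peaks had a protein-coding 5′ end within 1000 bp.

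Among the 25 strongest nuclear peaks, 18 lay beside a short RNA gene. snoRNA genes were beside 8 of them, tRNA genes beside 6, snRNA genes beside 4 and a miRNA gene beside 1. The snoRNA genes included T19B4.8 on chromosome I (5707046 to 5707119, signal value 114) and ZK265.10 on chromosome I (8259437 to 8259498, signal value 102). The snRNA genes were W05B2.8 in an intron of the dynein heavy chain gene dhc-4 on chromosome III (10989679 to 10989780, signal value 115), sup-6 on chromosome II (12944803 to 12944967, signal value 112.2), sls-2.1 (signal value 81.7) and sls-2.9. The last pair encode SL2 spliced leader RNAs, which are added to the 5′ ends of mRNAs from operons. The summit near sls-2.9 (signal value 82.2) lay 179 bp from that gene and inside the tRNA-Lys gene M01E5.t1 (13297673 to 13297745), so the peak was counted in both classes. Further down the list, peaks lay at or beside sls-2.2, sls-2.8 and sls-2.4. A peak on chromosome IV, at 11025962 to 11026417 with a signal value of 88.6, lay beside mir-51, and one on X, at 13145042 to 13145497 with 68.2, lay beside mir-54. A peak on chromosome II at 7200115 to 7200570 with a signal value of 66.9 had its summit in mrpr-1, the gene for the RNA of RNase MRP. The median signal value was 73.8 for the 44 nuclear peaks beside short RNA genes and 68.9 for the other 37 (two-sided permutation p = 0.0276, chosen after seeing the data).

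Of 612 nuclear tRNA genes, 23 (3.76%, exact 95% interval 2.40% to 5.59%) had an optimal summit within 250 bp, and 144 (23.5%) had a summit of the pooled list. The same shares were 17 of 346 (4.91%, interval 2.89% to 7.75%) and 14.5% for snoRNA genes, and 7 of 129 (5.43%, interval 2.21% to 10.9%) and 12.4% for snRNA genes. Genes for tRNA-Ala made up 6 of the 23 tRNA genes, and genes for tRNA-Asp and tRNA-Leu 3 each. With mitochondrial peaks counted as well, as fixed before the data were examined, tRNA genes lay beside 28 of 102 peaks against 9.51 for shifted positions and rRNA genes beside 4 against 4.02. The 4 classes tRNA, snRNA, snoRNA and miRNA passed the threshold in both counts. The miRNA result rests on 2 peaks, and it was lost with 100 bp in place of 250 bp (adjusted p = 0.102 by the permutation test), in the stronger 51 peaks (0.0713) and with replicate 2's own strongest regions (0.193).

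The share beside short RNA genes was highest among the strongest regions of all 3 lenient lists. In the pooled list, 72.0% of the 25 strongest nuclear regions (exact 95% interval 50.6% to 87.9%) and 53.3% of the next 75 (41.4% to 65.0%) lay beside such a gene, and 8.05% of those weaker than the first 600 did (6.03% to 10.5%). Each replicate showed this by itself. Among the 100 strongest nuclear regions, 46 lay beside a short RNA gene in replicate 1 and 45 in replicate 2, against 0.864 and 0.912 for shifted positions. Of the regions weaker than the first 5000, 240 of 12727 (1.89%) did so in replicate 1 and 134 of 7628 (1.76%) in replicate 2. Shifted positions gave means of 102 and 61.0, so these weak regions still lay above them (one-sided permutation p = 0.0001 in each). So did the pooled regions weaker than the first 600, with 50 against 5.25.

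**Figure D2:**
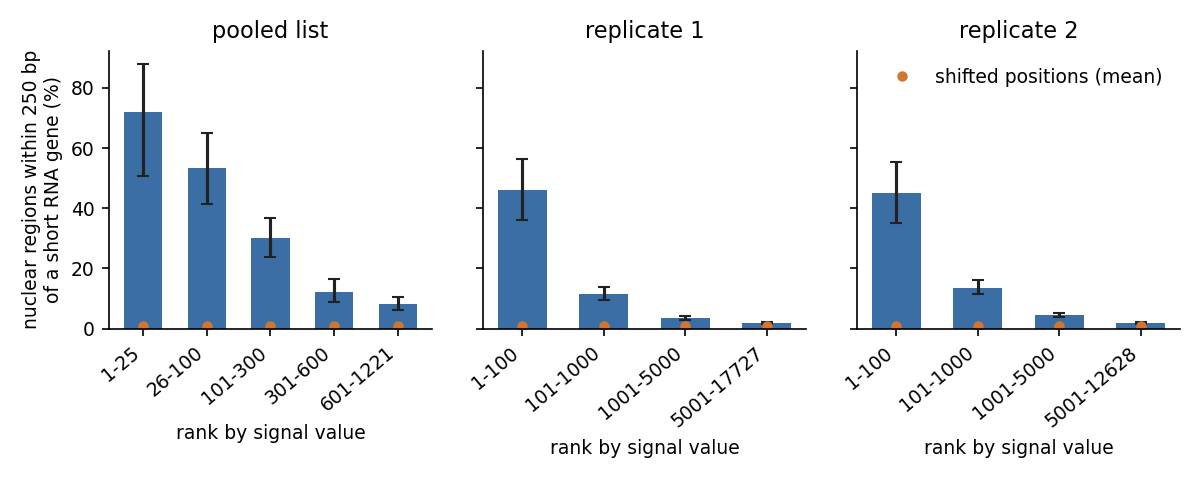
Percent of nuclear regions whose summit lies within 250 bp of a short RNA gene, by rank of the signal value, in the pooled list and in each replicate's list (bars, with exact 95% intervals). Orange points give the mean of 10000 circular shifts. The share falls from 72.0% of the 25 strongest pooled regions to 8.05% of the weakest group, and from 46.0% and 45.0% to 1.89% and 1.76% in replicates 1 and 2.

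X held more of the nuclear peaks than any other chromosome. Of the 81, 34 lay on X, a share of 42.0% (exact 95% interval 31.1% to 53.5%) against 17.7% of the nuclear length (two-sided exact binomial p = 4.35e-07). Chromosomes I, II and V held 12 peaks each, chromosome III 6 and chromosome IV 5. Of the 34 peaks on X, 15 lay beside short RNA genes, and 14 of those were beside tRNA genes. The 16 peaks beside snoRNA genes and the 7 beside snRNA genes lay on autosomes, 6 of the snoRNA peaks each on chromosomes I and V. X carries 276 of the 612 nuclear tRNA genes (45.1%), 33 of the 346 snoRNA genes and 3 of the 129 snRNA genes. Of the 37 nuclear peaks away from short RNA genes, 19 (51.4%, interval 34.4% to 68.1%) lay on X (two-sided exact binomial p = 3.28e-06, chosen after seeing the data).

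**Figure D3:**
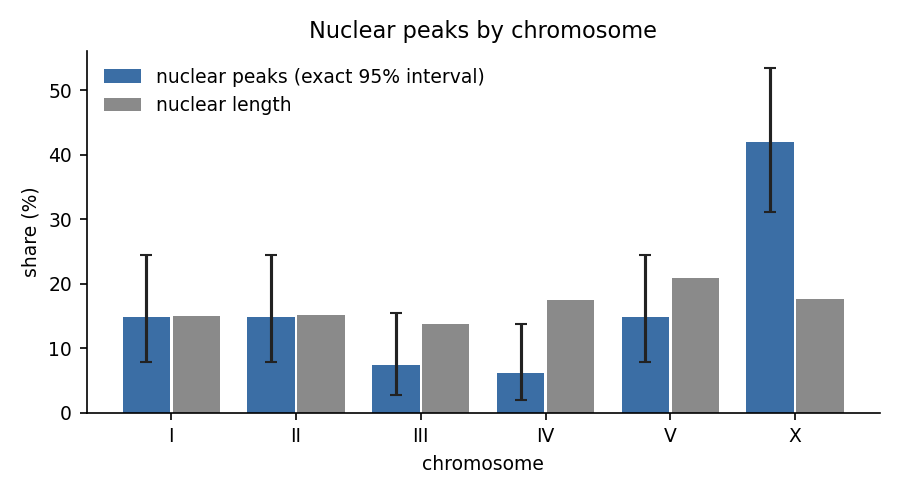
Share of the 81 nuclear peaks on each chromosome (blue bars, with exact 95% intervals) beside the chromosome's share of the nuclear length (grey bars). X holds 42.0% of the peaks and 17.7% of the length, and the interval of its share lies above its length share.

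On X, 5 peaks stood within 5757 bp of each other in a stretch without annotated genes. Their summits lay from 15389982 to 15395739, and their signal values ran from 72.2 to 117. The nearest protein-coding genes were svh-5, whose 5′ end lay 12158 bp before the first summit, and psa-3, which began 12192 bp after the last. The nearest annotated gene of any kind was the non-coding RNA gene F47C8.5 at 2099 bp. In each of these 5 peaks at least 96.7% of 31-base words occurred once in the genome. Other X peaks away from short RNA genes included those in introns of mom-1, a Wnt pathway gene, and cgt-2, and in coding exons of acdh-10 and nlp-67.

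Promoters of protein-coding genes held a smaller part of the peaks than short RNA genes did. Among nuclear peaks 25 of 81 summits (30.9%, exact 95% interval 21.1% to 42.1%) fell in a promoter, against 20.6% of shifted positions (one-sided permutation p = 0.0176). Over all 102 peaks, mitochondrial ones included, the share was 41.2% (31.5% to 51.4%) against 32.2% (permutation p = 0.0175). Of the 37 nuclear peaks away from short RNA genes, 13 were in promoters, 11 were intergenic and 8 in introns. Those at promoters included hda-11, which encodes a histone deacetylase (chromosome V, 10525894 to 10526349, signal value 65.4, summit 62 bp upstream), cpl-1, which encodes a cathepsin L (chromosome V, 16595024 to 16595479, signal value 72.3, summit 94 bp downstream of the 5′ end), ins-39 on X, which encodes an insulin-like peptide (signal value 68.9), and akap-17A on chromosome III (65.4, with ranks 4008 in replicate 1 and 49 in replicate 2). With 500 bp in place of 1000 bp the share was 24.5% against 20.98% (one-sided permutation p = 0.199). In the 51 strongest peaks, of which 21 were mitochondrial, it was 45.1% against 43.7% (one-sided permutation p = 0.462). With genes of every biotype, RNA genes included, it was 79.4% against 43.7% (permutation p = 0.0001).

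Non-coding RNA genes were the 1 feature class of 6 past the threshold. They held 7 summits (6.86%) against 0.781% of shifted positions, with an adjusted p of 0.0006 in the one-sided permutation test, after promoters and protein-coding genes had been taken out. Promoters had an adjusted p of 0.0525. Introns held 27 summits (26.5% against 23.5%) and intergenic sequence 18 (17.6% against 20.7%). Coding exons held 8 summits, 7.84% against 20.6% of shifted positions. In chromosome centres, taken as the middle one of 3 equal parts, 33 of 81 nuclear peaks (40.7%, exact 95% interval 29.9% to 52.2%) were found, which did not differ from 33.3% by the two-sided exact binomial test (p = 0.159).

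None of the 24 gene lists passed the test among the 41 protein-coding genes with a summit within 1000 bp of their 5′ end. By Fisher's exact test 0 lists passed after adjustment and 0 had an unadjusted p under 0.05. The lists had 4 bound members in all. These were rps-26, a cytosolic ribosomal protein gene next to the snoRNA gene F39B2.14, the nuclear hormone receptor gene nhr-255 next to a tRNA-Leu gene, the chemoreceptor gene sre-23 next to the snoRNA gene ZK265.10, and hda-11 of the chromatin list. No bound gene came from the SKN-1 endomesoderm network, the sdz genes, the histones, the vitellogenins, the collagens or the germline list. Only 0.0123 (vitellogenins) to 0.351 (collagens) bound members were expected in each of these lists, so their absence says little. With replicate 1's own 102 strongest regions, 2 lists passed, ribosomal proteins with rpl-18A, rps-10 and rps-26 (adjusted p = 0.0152 by Fisher's exact test) and heat shock proteins with hsp-12.3 and hsp-90 (adjusted p = 0.0171). With those of replicate 2 no list did.

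The short words that passed at the summits depended on the control and on the peaks used. Of 2073 words of 6 bases, 6 passed the threshold over all 102 peaks, 3 of them more frequent at summits than in the flanks. GCGCCA was present in 10 of 102 summit windows and 0 of 204 flank windows (adjusted p = 0.0258 by Fisher's exact test), CCACTC in 13 and 3, and AGTGGC in 10 and 1 (adjusted p = 0.0371 for both, by the same exact test). TTAAAA, TTTAAA and ATATCA were less frequent at summits, with 10, 4 and 0 windows against 60, 40 and 23 in the flanks. GC content within 50 bp was 46.4% ± 8.93 (SD, n = 81) at nuclear summits and 36.4% ± 8.53 (SD, n = 162) in the flanks. In nuclear peaks 5 words passed, GCGCCA, AGTGGC and TTAAAA among them. No word passed with windows of 25 bp, in the 51 strongest peaks or with replicate 1's own strongest regions. With the lowest-signal regions as control 6 words passed, all more frequent at summits, and 1 of them, CCACTC, was among the 6 above (for GCGCCA and AGTGGC adjusted p = 0.0833 by Fisher's exact test). With replicate 2's own strongest regions 10 words passed, 2 of them among the 6 above and GCGCCA not. The exact test counts windows as independent. Yet 20 of the 81 nuclear summits lay beside tRNA genes, whose sequence is largely repeated among gene copies. Whether the passing words only repeat such gene sequence was not tested, so their p-values may be too small.

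The replicates shared more of their strongest regions than shifted positions did. Of the 102 strongest regions of replicate 1, 49 (48.0%, exact 95% interval 38.04% to 58.2%) overlapped the 102 strongest of replicate 2, against 11.7% after shifting (one-sided permutation p = 0.0001, the smallest possible). Among nuclear regions 32 of 81 were shared (39.5%, 28.8% to 50.99%), against 0.115% after shifting. Among the 1000 strongest regions of each replicate 21.6% were shared, against 2.29% after shifting. Of the 102 optimal peaks, 51 ranked within the first 102 regions of both replicates, and so did 22 of the 44 nuclear peaks beside short RNA genes and 9 of the other 37. The lowest ranks among optimal peaks were 4360 in replicate 1 and 9977 in replicate 2. Across the optimal peaks with a region in both replicates, all but 1 of the 102, Spearman's rho of the signal values was 0.554 (bootstrap 95% interval 0.350 to 0.711). Within the 81 nuclear peaks it was 0.140 (−0.117 to 0.370), and this interval includes 0. These peaks were already selected from both replicates, and some mitochondrial peaks share a replicate region, so rho describes the selected peaks only.

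**Figure D4:**
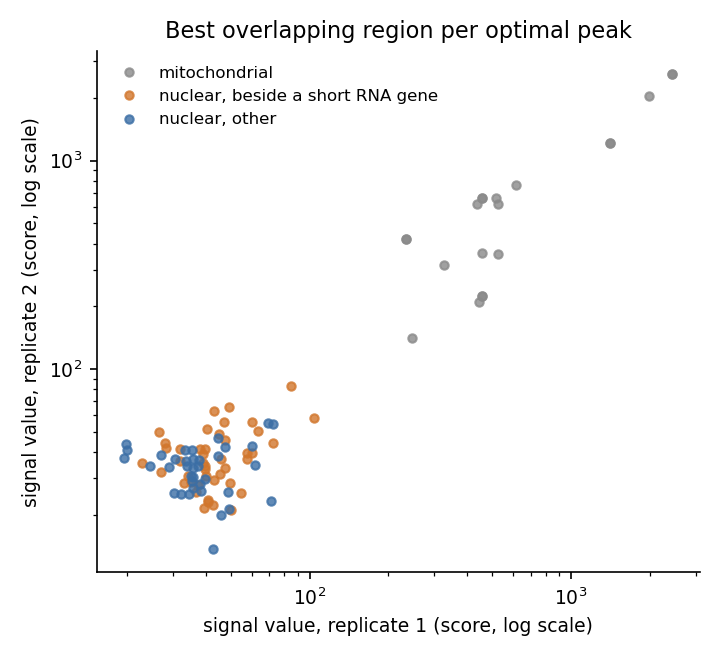
Signal value of the best overlapping region in replicate 1 (x axis, score, log scale) and replicate 2 (y axis, score, log scale) for each optimal peak with a region in both. Mitochondrial peaks (grey) sit apart from nuclear peaks, and the nuclear peaks beside short RNA genes (orange) and elsewhere (blue) form 1 cloud with rho = 0.140.

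Neither the tagged gene nor unc-119 held an optimal peak. unc-119 is the usual rescue marker of such strains, and whether this strain carries it was not checked here. sdz-38 (WBGene00014131) lies on chromosome II at 9980886 to 9981860, on the minus strand. The nearest optimal peak, at 9993289 to 9993744 with a signal value of 63.5, lay in an intron of the galectin gene lec-3, and its summit was 11657 bp from sdz-38. The lenient lists held many regions around the tagged gene. Within 20 kb of it, 25 regions of replicate 1 and 14 regions of replicate 2 had their summit, against medians of 7 and 5 over nuclear protein-coding genes and upper ends of the central 95% range of 16 and 12. In the pooled list 7 regions did, with a median over genes of 0 and an upper end of 3. unc-119 (WBGene00006843) lies on chromosome III at 10902641 to 10908935. It had 4 and 5 regions within 20 kb in replicates 1 and 2, and its nearest optimal summit was 80747 bp away.

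**Figure D5:**
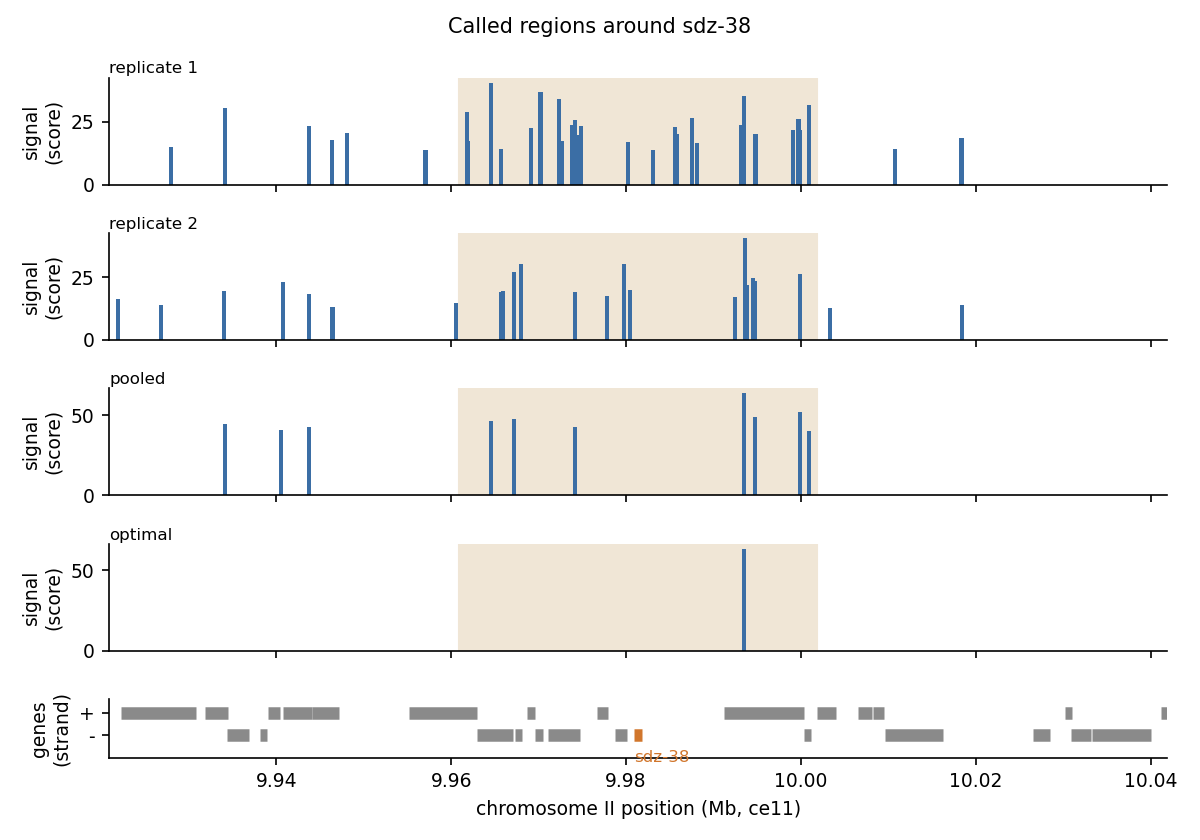
Called regions within 60 kb of sdz-38 on chromosome II (x axis, Mb, ce11), with the signal value (y axis, score) of each region in replicate 1, replicate 2, the pooled list and the optimal list, above the protein-coding genes by strand (sdz-38 in orange). The shaded window of 20 kb to either side holds 25 regions of replicate 1 and 14 of replicate 2.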

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

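The tests of the words of single short RNA genes, of the X share in weak regions and of the coverage of the mitochondrial genome were chosen only after the result was seen, and the X shares away from short RNA genes and with the densest stretch counted once were chosen after seeing the lists.

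Pooled regions outside the optimal list also lay at short RNA genes. Of 1140 nuclear regions of the pooled list outside the optimal list, 161 (14.1%) had a summit within 250 bp of a short RNA gene, against 9.81 for shifted positions (one-sided permutation p = 0.0001). tRNA genes lay beside 113 of them, snoRNA genes beside 33 and snRNA genes beside 13, while miRNA genes, beside 4 against 1.82 for shifted positions, did not pass (one-sided permutation p = 0.114). This stood out because these regions lie outside the optimal list, on which the counts of peaks by RNA class rest.

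Short RNA genes beside 44 of 81 nuclear peaks were weighed against 3 technical explanations. GC content at the summits is argued against, since positions matched on GC content lay beside short RNA genes 1.12 times per set of 81 on average and at most 8 times. Reads shared between identical gene copies are argued against for the peaks beside snoRNA genes, since a median of 100% of the 31-base words of the 17 snoRNA genes with a summit occurred once in the genome (lowest gene 100%). For tRNA genes this explanation stays open: the median was 0% in the 23 genes with a summit and 0% in the 589 without one, so the class itself fixes the value. For the 7 snRNA genes it stays open with a median of 51.9%. The median over whole peaks, 94.5%, decides nothing, because a median of 75.0% of a peak's words lay outside the short RNA genes and would stay unaffected by repeated genes. Capture of all strongly transcribed chromatin stays open: 1 of 78 cytosolic ribosomal protein genes (1.28%, exact 95% interval 0.0325% to 6.94%) had a summit within 250 bp, and the interval for snoRNA genes (2.89% to 7.75%) overlaps that. The only such gene with an optimal summit within 1000 bp of its 5′ end, rps-26, lies next to the snoRNA gene F39B2.14. Both shares may therefore count the same peak. The design has a single group, so no biological explanation from a comparison of groups was tested, and a library without the tagged protein is not analysed here.

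The excess of nuclear peaks on X is not accounted for by tRNA genes or by the 5 neighbouring peaks. Away from short RNA genes 51.4% of peaks lay on X, and with the densest 20 kb of X summits counted once 39.0% did (exact 95% interval 28.0% to 50.8%), both above 17.7% of the length. The weak background regions also leaned to X, with 24.6% in replicate 1 and 24.3% in replicate 2 of the regions whose signal ranked below the middle of the list (upper bounds 25.5% and 25.4%). A lean of that size may account for part of the excess, but not for all of it, since the lower bound for the peaks was 31.1%. Stronger regions leaned further to X, with 36% in replicate 1 and 35.7% in replicate 2 at nuclear ranks 101 to 1000. In the pooled list X held 38.7% of nuclear regions, and 36.2% of those ranked 601 to 1221. The interval for the peaks (31.1% to 53.5%) includes these values. Whether a background lean that grows with signal accounts for the whole excess therefore stays open. No biological explanation of this pattern was tested.

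For the mitochondrial peaks, reads shared with nuclear copies of mitochondrial DNA are argued against, since a median of 100% of their 31-base words occurred once in the genome. Uneven coverage of a high-copy genome stays open. Regions covered 39.3% of the mitochondrial genome in replicate 1 and 44.6% in replicate 2. These shares lie between limits of above 50% and under 25%, which were chosen only after the result was seen. A covered share alone cannot tell uneven coverage from binding, because it depends on which regions were called. The depth of the control library is not analysed here. No biological explanation of this pattern was tested.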

How the results depend on the processing

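No paired analysis was possible because the study has 1 group. Of 53 alternative values of the results that answer a comparison, 40 stayed close to the value first fixed, in direction and side of the threshold for tests and in number for counts, among them the overlap of the replicates (21.6% to 48.0% shared), the 4 RNA classes (3 or 4 in every setting) and the share on X (38.96% to 51.4%, both ends from alternatives chosen after seeing the data). The stronger 51 peaks are a lower number by construction. They include all 21 mitochondrial peaks beside 30 nuclear ones, so their rho spans the gap in signal between those groups. In the stronger 51, promoters held 45.1% of summits, 0 words of 6 bases passed and rho was 0.813. Promoters of 500 bp held 24.5% of summits. Equal numbers need not mean the same words: with the lowest-signal regions as control 6 words passed, 1 of them shared. Windows of 25 bp gave 0 words and windows of 100 bp gave 13. With nuclear peaks alone, an alternative chosen after seeing the data, rho was 0.140. With either replicate's own regions in place of the optimal list, the words numbered 0 to 10, the feature classes 1 to 2, the gene lists 0 to 2 and the share in chromosome centres 31.7% to 38.4%, the lower of which lies below 33.3%. miRNA genes passed in neither the 100 bp setting, the stronger 51 peaks nor replicate 2's own regions, each with 1 peak. Signal values are scores without a stated scale and the lists hold no read numbers, so depth limits were not computed.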

Other observations

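The tests of peaks away from short RNA genes and of snoRNA genes without an optimal summit were fixed before their results were seen, and the tests of snoRNA genes with an optimal summit and of the tagged gene were chosen only after the result was seen.

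Matches to the B box, the internal promoter element of RNA polymerase III, were sought in short RNA genes and near them. A match alone does not show such an element. Within 100 bp, 24 of the 44 nuclear summits beside short RNA genes had a match (54.5%). The counts were 15 of 20 beside tRNA genes, 8 of 16 beside snoRNA genes and 1 of 7 beside snRNA genes. Flanking windows held a match in 4.55% of cases for nuclear peaks beside short RNA genes and in 8.11% for the others. A match (GTTCGANNC or GTTCAANNC) lay in or within 100 bp of 591 of 612 nuclear tRNA genes, so matches at summits beside tRNA genes say little about binding. rpr-1 and mrpr-1, the genes for the RNAs of RNase P and RNase MRP, held 1 peak each.

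Among snoRNA genes, those with a match to the B box held a summit more often. Of 64 nuclear snoRNA genes with a match in the gene or within 100 bp of it, 10 (15.6%, exact 95% interval 7.76% to 26.9%) had an optimal summit within 250 bp, against 7 of 282 without one (2.48%, 1.00% to 5.05%; one-sided Fisher's exact p = 0.000163). This comparison followed from matches already seen at these summits, so it does not count as evidence by itself. Among the other snoRNA genes, 13 of 54 with a match (24.1%, 13.5% to 37.6%) had a summit of the pooled list within 250 bp, against 20 of 275 without one (7.27%, 4.50% to 11.01%; one-sided Fisher's exact p = 0.000689). Those genes differ from the ones above, but the libraries are the same. A candidate explanation, as a hypothesis, is that the signal at snoRNA genes gathers at those with an internal RNA polymerase III promoter. Among snRNA genes 0 of 11 with a match and 7 of 118 without one had an optimal summit, too few to compare. For tRNA genes the same comparison has little contrast (3.72% against 4.76% with a summit).

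Peaks away from short RNA genes could mark RNA polymerase III promoters that the annotation lacks. A B-box match lay within 100 bp of 4 of these 37 summits (10.8%) and in 6 of 74 flanking windows (8.11%; one-sided Fisher's exact p = 0.441). The 37 include the summits in rpr-1 and mrpr-1, which the annotation lists outside the short RNA classes used here. With 37 peaks this leaves the question open.

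The regions around sdz-38 may come from extra copies of the DNA that was used to insert the tagged gene. The count behind it, 14 regions within 20 kb in the replicate with fewer and 25 in the other, is the observation that prompted it, so it does not count as evidence for it. Replicate 1's number is above that of 99.7% of nuclear protein-coding genes and replicate 2's above that of 98.5%. Around unc-119 the numbers were 4 and 5. They say little about extra copies, since whether this strain carries added unc-119 DNA was not checked here. Binding of the tagged protein near its own gene could also raise these counts. The counts do not separate it from extra copies, and how the regions spread around the gene was not tested. The replicate lists were made with a control alignment, but the control library is not analysed here. Whether it would tell these explanations apart is therefore unknown.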
